A study of Gallus gallus with 3 samples.

How the data were processed

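Granulosa cells are the somatic cells of the ovarian follicle that lie next to the oocyte. Their RNA was sequenced from chicken follicles at 3 stages, with 1 library per stage: follicles of 6 mm in diameter, which precede selection into the preovulatory hierarchy, F5 follicles, which are early preovulatory and grow fast, and F1 follicles, the largest of the hierarchy, shortly before ovulation. Per the labels' protocols, messenger RNA was enriched by its poly-A tails and reverse transcribed from random hexamers. How many hens or follicles gave each library is not given in the sources used here, and neither is whether reads were counted by strand.

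Per the submitters' processing notes, reads were aligned with TopHat2 version 2.0.12 and counted with HTSeq version 0.6.1. The genome build is not given in the sources used here, so positions are printed as the files give them. The authors deposited FPKM values (reads scaled by gene length and by the library's read total) for each gene of each library, with the gene's position, a gene name and function annotations. Each of the 3 files held 19309 genes with a value, and 2 lines per file without a gene identifier or value were not used. Of these genes, 2201 have identifiers that are not Ensembl ones. Symbols were taken from the files where they match a symbol of NCBI RefSeq's gene table for the assembly GRCg7b or have the form of a gene symbol, which gave 12282 symbols from the gene name column and 319 from the KEGG column. That table was used for symbols only.

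The FPKM values of all 17019 genes above 0 in any library were whole reads divided by a whole length and by the library total, with a largest relative deviation of 1.92e-14. The library totals recovered from these steps were 14923359 reads for 6 mm, 14137511 for F5 and 14086626 for F1. Per gene the smallest whole numbers that fit were taken as its reads, and they came to 94.7%, 93.8% and 94.8% of the totals, so counting intervals are slightly too wide and floors slightly too high. The recovered length divided the length column of the files for 7.53% of genes, so that column was not the length behind the values. Exact 95% intervals of FPKM values and of FPKM ratios were computed from these reads. A gene without reads in 1 library was given a floor of 3 reads there, and its fold is given as at least that against the floor. The exact 95% limit for 0 reads is wider, and its lower limit of the fold is given beside it. Intervals and floors cover counting error only.

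With 1 library per stage there was no test, no standard error and no replicate check. Each comparison used the difference of log2(FPKM + 1) between 2 libraries, which understates the difference of low genes, over genes with an FPKM of at least 1 in either library. Genes were counted at a difference of at least 1 (2-fold) and of at least 2 (4-fold). The comparisons were F5 against 6 mm, F1 against F5 and F1 against 6 mm. For scale, 20 draws of counting noise alone were simulated per comparison. Over all 3 libraries, each gene was also classed by its steps from 6 mm to F5 and from F5 to F1, and pairs of libraries were correlated across genes, which are not replicates.

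Before the data were examined, 28 gene lists were fixed. They cover steroidogenesis, cholesterol synthesis and uptake, gonadotropin and cAMP signalling, granulosa identity and the inhibin family, BMP and TGF-beta signalling, WNT and NOTCH signalling, EGF receptor ligands and MAPK, the cell cycle, cell cycle inhibitors and cyclins D, ovulation and prostaglandin genes, extracellular matrix and basal lamina, cell junctions, the zona pellucida, growth factors, the circadian clock, apoptosis, immediate early genes, heat shock and the unfolded protein response, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, reference genes, and markers of theca and smooth muscle, endothelium, erythrocytes, leukocytes, oocyte and germ cells, and surface epithelium and oviduct. A list's median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and lists outside the central 95% are reported as lying above or below their random lists. This describes the libraries, not the stages. Of the marker lists' genes, another list holds 2 of 22 for theca and smooth muscle, 2 of 17 for endothelium, 0 of 19 for erythrocytes, 2 of 30 for leukocytes, 4 of 21 for oocyte and germ cells and 3 of 20 for surface epithelium. The erythrocyte list had fewer than 3 measured members in each comparison and got no median. The other 27 lists gave 81 medians, of which about 4.05 would lie outside by chance.

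Some genes that the rule below takes are not reported here. The genes named were fixed by rule: per comparison the 10 largest differences in each direction among genes with a symbol and an FPKM of at least 10 in either library, a set of core genes of follicle biology, and up to 4 members of each list with the largest differences at an FPKM of at least 5. Where a symbol has several gene entries the one with the highest mean FPKM was used. This holds for COL3A1, ACTG2, COL2A1, SMAD7, KRT7, HSPG2, RPL34 and PIWIL1. Symbols from the KEGG column are less certain. Among the genes named they include COL1A1, COL2A1, SMAD2, SMAD7, ACTG2, IGLL1, CRIP1, KRT7, PPARG, PTGS2, DUSP6, ANGPT2 and BHLHE41. Values of keratins, actins, collagens, ribosomal proteins and fatty acid-binding proteins, whose copies can share reads, are uncertain for single members.

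The calculations were tested on simulated reads with 50 genes changed per fold and direction. Read recovery returned the drawn reads, up to a common divisor, for 99.9948% of 19309 genes. The library totals were given to it, so the step that finds the totals was not tested. All genes made 4-fold higher or lower were counted in each comparison. Of genes made 1.5-fold different, 2% at most were counted. Unchanged genes were counted in 122 of 11602 cases for F5 against 6 mm, 104 of 10774 for F1 against F5 and 118 of 11297 for F1 against 6 mm. Lists of 20 genes shifted by 0.5 lay outside their random lists in 20 of 20 cases per comparison, and unshifted ones in 0 of 20. Apart from the genes changed on purpose, the simulated libraries differed by counting noise only. Random lists spread more in the data, as from -0.96 to -0.09 for steroidogenesis in F1 against 6 mm. The share of shifted lists found thus does not carry over to the data.

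Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter at an FPKM of 5, and rescaling by the median ratio of genes at an FPKM of at least 10 in all libraries, to the same sum, to the same upper quartile, and to the same sum without the 50 most abundant genes. Leaving ZP3 out of the library totals was added after the data were seen. Gene Ontology terms of the files with 15 to 100 members were explored after the data were seen, with 2000 random lists per term. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.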

Results

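Transcript levels were measured by RNA sequencing in granulosa cells of the hen at 3 stages of follicle growth. The stages were the 6 mm follicle, not yet selected for the preovulatory hierarchy, the F5 follicle, which has entered it and grows fast, and the F1 follicle, the next to ovulate. Each stage had 1 library, of 14923359 reads for 6 mm, 14137511 for F5 and 14086626 for F1. No difference below has a replicate check, and all bracketed intervals are exact 95% intervals that cover counting error only. Of 19309 genes, 12070 reached an FPKM of 1 in 6 mm, 11432 in F5 and 10283 in F1. The most abundant transcript in F1 was ZP3, a glycoprotein of the egg's inner perivitelline layer, with at least 13.4% of all reads, against 1.80% in F5 and 0.690% in 6 mm. In 6 mm the gene ENSGALG00000027090, to which the files give no name, held at least 14.3% of reads (chromosome 4, 85449698 to 85458910, genome build not given in the sources used here). Across 12812 genes, which are not replicates, log2(FPKM + 1) correlated with a Pearson r of 0.892 between 6 mm and F5, 0.8998 between F5 and F1 and 0.810 between 6 mm and F1. Spearman's rho was 0.892 between 6 mm and F5, 0.890 between F5 and F1 and 0.799 between 6 mm and F1.

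The comparison of F5 with 6 mm asked what differs between granulosa cells before and after a follicle is selected. STAR, which moves cholesterol into mitochondria, stood at an FPKM of 55.1 against 2.14, 25.7-fold higher (17.6 to 38.9). CYP11A1, the side-chain cleavage enzyme, was 47.6-fold higher (32.1 to 73.9). NR5A2, a nuclear receptor that activates steroidogenic genes, was 480.5-fold higher (296 to 841). INHA, the alpha subunit of the inhibins, was 35.1-fold higher at 4631 against 132 (32.9 to 37.4). AMH, a hormone of small growing follicles, was 21.1-fold lower at 18.2 against 384 (19.6 to 22.7).

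Among the largest differences of genes with a symbol in F5, CEL, a bile salt-activated lipase, had an FPKM of 305 and no reads in 6 mm, at least 2673-fold higher against a floor of 3 reads (exact lower limit 2173). PGF, a ligand of the VEGF family, was at 855 against 11.4, the potassium channel KCNH2 at 139 against 0.936. The fatty acid-binding protein FABP5 was at 162 against 2.52, the actin regulator INF2 at 126 against 3.24, the sorting receptor SORL1 at 151 against 4.17, and TMEM72 at 162 against 1.27. Among those higher in 6 mm, COL1A1, a fibrillar collagen whose entry is a fragment on an unplaced scaffold, had 276 in 6 mm and no reads in F5, at least 418-fold lower against that floor (exact lower limit 339). COL3A1 was 234-fold lower (165 to 345), the matrix proteoglycan DCN at least 200.5-fold lower against the floor (exact lower limit 163), and TAGLN and DES, proteins of the smooth muscle cytoskeleton, stood at 163 and 61.7 in 6 mm against 0.0587 and 0.157 in F5. ACTG2, a smooth muscle actin, was at 132 against 0.312. The caveolar protein PTRF was at 88.8 against 0.229, the cobalamin-binding protein GIF at 104 against 0.166, IGLL1, an immunoglobulin light chain, at 87.2 against 0, and COL2A1 at 73.4 against 0. The COL2A1 entry, like that of COL1A1, lies on an unplaced scaffold and takes its symbol from the KEGG column, so its name is uncertain.

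Of 19 measured genes of steroidogenesis, 7 were at least 2-fold higher and 4 lower in F5, and the list's median of 0.39 lay above its random lists (percentile 99.7). HSD3B2, which makes progesterone, was at 487 against 67.3, and HSD17B2, which inactivates sex steroids, at 0.710 against 12.5. CYP17A1, needed for androgen synthesis, was low in both libraries at 3.66 and 2.12, and CYP19A1, the aromatase, had 1.53 in 6 mm and no reads in F5. Cholesterol synthesis and uptake lay above its random lists too (5 of 18 higher, 0 lower, median 0.51, percentile 99.7). The sterol-regulated transcription factor SREBF2 was at 158 against 52.7, CYP51A1 at 65.3 against 30.8 and EBP at 6.09 against 1.25. In the list of granulosa identity and the inhibin family, 5 of 19 were higher and 4 lower, with a median of 0.52 (percentile 99.95). Its beta subunits INHBA and INHBB were at 9.48 and 893 in F5 against 1.09 and 321. FST, which binds activin, was at 30.4 against 290.1, the transcription factor WT1 at 2.21 against 31.7, and FOXL2, a transcription factor of granulosa cells, at 967 against 675.

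The zona pellucida list split, with 2 of 6 members higher and 4 lower and a median of -1.78 (percentile 0). ZPD was at 1181 against 42.4 and ZP3 at 13094 against 5011, while ZP2 was at 33.4 against 183, ZP4 at 2.88 against 13.2 and ZP1 at 0.0488 against 11.2. Of 22 ovulation and prostaglandin genes, 12 were lower and 1 higher (median -1.38, or -1.07 with genes without reads at their floor, percentile 0). The proteases MMP9, PLAU and PLAT stood at 18.4, 28.2 and 10.9 in 6 mm against 0, 1.64 and 1.76 in F5, and the progesterone receptor PGR was 45.0-fold lower in F5 (12.1 to 377). PPARG, a lipid-sensing nuclear receptor, was 16.3-fold higher there (13.0 to 20.8). Extracellular matrix and basal lamina had 14 of 29 lower and 3 higher (median -0.70, percentile 0.02). COL6A1 was at 0.0616 against 27.7 and COL6A2 at 0.204 against 30.8, with the basement membrane protein NID2 higher at 154 against 21.8. Cell junctions had 5 of 18 lower and 0 higher (median -0.65). The tight junction protein CLDN1 was at 9.91 against 41.3 and the cadherin CDH3 at 68.3 against 181. Growth factors had 4 of 18 higher and 5 lower with a median of -0.52 (-0.31 at the floor) but a mean of 0.09. They included IGFBP4, which binds insulin-like growth factors, at 2011 against 357, VEGFA at 152 against 54.1 and ANGPT2 at 2.38 against 17.2. With a filter at an FPKM of 5, extracellular matrix (percentile 4.58) and growth factors (7.92) came to lie within their random lists, as did junctions without a filter (6.63) and the granulosa and inhibin list with a pseudocount of 5 (97.3).

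Immediate early genes lay below their random lists in F5 (5 of 12 lower, 0 higher, median -0.91). FOS was at 8.87 against 40.1, MYC at 7.30 against 23.8 and EGR1 at 0.342 against 6.70. The cell cycle list had 6 of 48 lower and 1 higher, with a median of -0.49 (percentile 0). TYMS, which makes thymidylate, was at 45.9 against 124, the mitotic kinase AURKA at 23.4 against 63.6 and the cyclin CCNB2 at 89.3 against 213. Reference genes had a median of -0.20, with 1 of 24 lower. ACTB was at 1574 against 2211 and GAPDH at 1130.4 against 2147. Apart from the markers of other cell types given below, the remaining lists lay within their random lists, though single members differed widely. In the WNT and NOTCH list (3 of 24 higher, 6 lower, median -0.12), the ligand WNT4 was 13.4-fold higher in F5 at 1885 against 141 (12.9 to 13.9), WNT6 was at 27.2 against 104 and the secreted protein DKK3 was 4.16-fold higher (3.91 to 4.43). In BMP and TGF-beta signalling (6 of 26 higher, 5 lower), the activin and TGF-beta signal transducer SMAD2 was at 1701 against 221, and ID1 and ID3, known as targets of BMP signalling, were at 115 and 127 against 31.3 and 39.6. In gonadotropin and cAMP signalling (2 of 17 higher, 0 lower, median 0.11), the adenylate cyclase ADCY3 was at 268 against 62.9, and the receptors FSHR and LHCGR were close, at 42.4 and 12.6 against 31.5 and 9.58. EGF receptor ligands and MAPK had 6 of 16 lower and 0 higher (median -0.51, DUSP6 at 0.988 against 5.21), cell cycle inhibitors and cyclins D 2 of 12 higher (median 0.21, GADD45B at 47.5 against 3.15). The clock had 3 of 15 higher (median 0.24, NPAS2 at 8.36 against 1.30), and apoptosis 2 of 20 higher and 1 lower (median 0.09, BMF at 7.61 against 45.7). Heat shock had 2 of 30 lower (median 0.27, HSPB1 at 0.285 against 37.8), glycolysis 4 of 22 higher and 1 lower (median 0.01, PFKFB3 at 188 against 38.8). Neither the 37 nuclear genes of oxidative phosphorylation (median 0.18) nor the 50 ribosomal protein genes (median 0.13) held a member that differed 2-fold. Both of these medians, and those of gonadotropin signalling and apoptosis, changed sign when the libraries were scaled to the same sum. The BMP and TGF-beta and the glycolysis medians, near 0, changed sign under 4 of 5 scalings.

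Markers of other cell types were higher in 6 mm beside these gene groups. Of the zona pellucida genes, ZP2 and ZP4 are members of the oocyte list too. Whether other cells in the 6 mm material gave the lower matrix, protease and zona pellucida genes of F5 was not tested. Of 19 markers of theca and smooth muscle, 15 were at least 2-fold lower in F5 and 0 higher (median -2.70, or -1.91 with genes without reads at their floor). Endothelial markers had 7 of 12 lower (median -1.13, at the floor -1.06, EMCN at 7.56 against 52.6), leukocyte markers 10 of 15 (median -1.29, the antigen-presenting protein BLB1 at 5.46 against 30.3). Lower were also oocyte and germ cell markers, 9 of 15 (median -1.38, the oocyte factors ZAR1 and BMP15 at 3.00 and 5.61 against 17.8 and 18.3), and surface epithelium 6 of 10, with 1 higher (median -2.32, at the floor -1.76, the keratins KRT7 and KRT19 at 1.29 and 3.17 against 83.3 and 91.0). All 5 medians lay below their random lists, but with a filter at an FPKM of 5 the endothelial list did not (percentile 38.3). Of the red cell markers, HBAA, chosen after its values were seen, was at 4.23 in 6 mm from at least 7 reads and at 0 in F5.

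**Figure D1:**
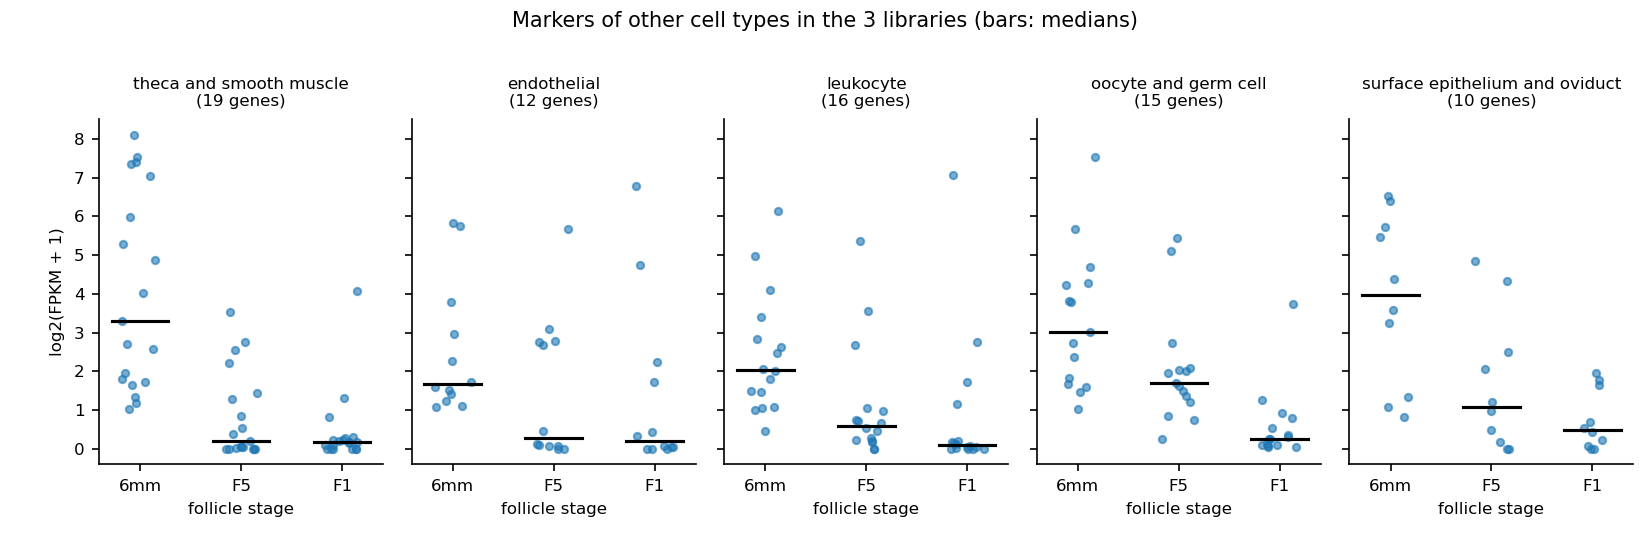
Levels of marker genes of 5 other cell types in each library. Each point is 1 gene with an FPKM of at least 1 in some library, the vertical axis is log2(FPKM + 1), the horizontal axis the follicle stage, sideways scatter is random and bars are medians. Of the 19 markers of theca and smooth muscle, 15 were at least 2-fold lower in F5 than in 6 mm.

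In all, 964 of 12611 genes were at least 2-fold higher in F5 and 1356 lower, and 263 and 247 differed at least 4-fold, where simulated counting noise alone gave 114 genes at 2-fold in both directions together. Lower genes were 58.4% of those 2-fold different and 71.0% (760 higher, 1861 lower) when the libraries were scaled to the same sum, which moved the median of all genes from -0.13 to -0.31. The excess of lower genes turned with a pseudocount of 5 (482 higher, 456 lower, 48.6% lower). Relative to the median gene 1161 were higher and 1090 lower, but that centring takes out a shift of all genes by construction.

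Between F5 and F1 the comparison spans the rapid growth phase up to the time before ovulation. The receptor of luteinizing hormone, LHCGR, was 37.6-fold higher in F1 at 472 against 12.6 (34.1 to 41.5), and FSHR was 2.63-fold lower at 16.1 against 42.4 (2.42 to 2.86). STAR was 10.9-fold (10.1 to 11.8), CYP11A1 4.49-fold (4.21 to 4.80) and HSD3B2 3.98-fold higher (3.92 to 4.04). INHBB was 515-fold lower at 1.74 against 893 (329 to 855) and WNT4 132-fold lower at 14.3 against 1885 (118 to 149). Of 48 cell cycle genes, 46 were at least 2-fold lower in F1 and 0 higher.

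**Figure D2:**
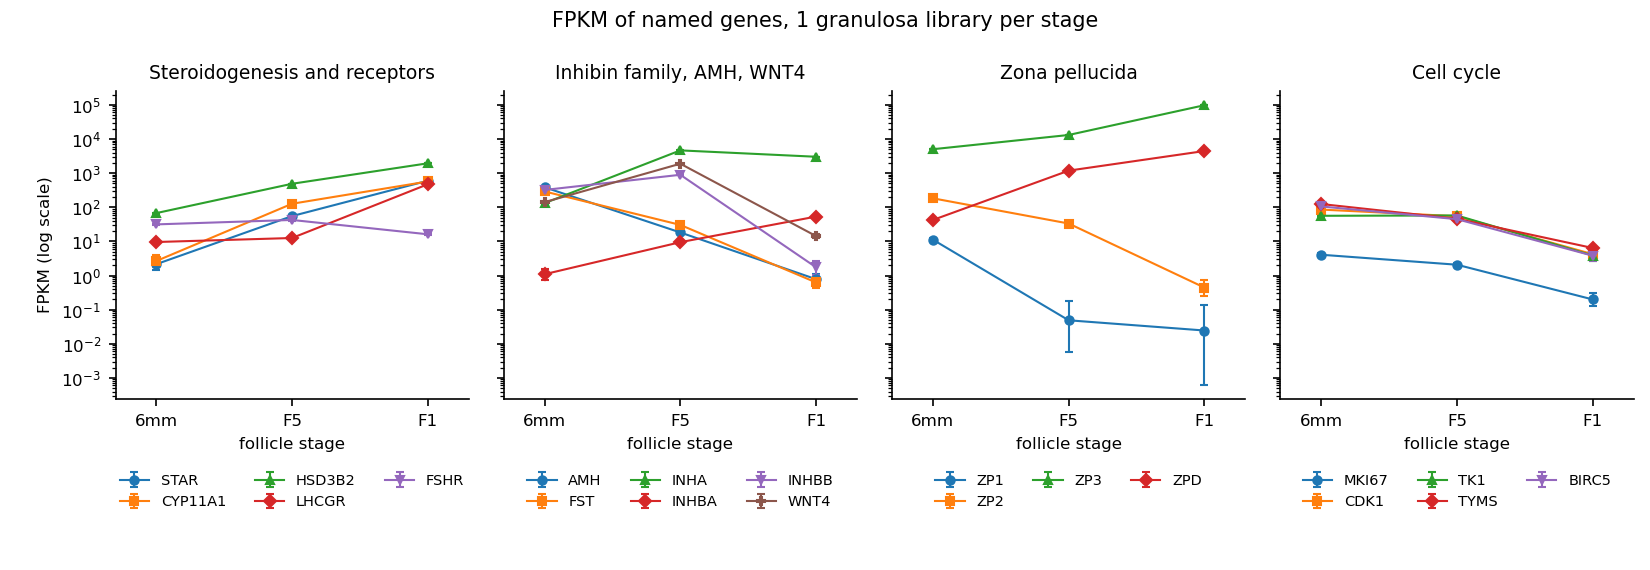
FPKM of 20 genes in the 6 mm, F5 and F1 libraries on a log axis, with exact 95% intervals for counting error as bars and lines that join the stages. STAR went from 2.14 through 55.1 to 599, AMH from 384 through 18.2 to 0.779, and ZP3 from 5011 through 13094 to 97522.

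Further genes far higher in F1 were CRIP1, a LIM domain protein, at 193 against 1.78, RPH3A, an effector of vesicle transport, at 111 against 2.65, EPAS1, a hypoxia-inducible transcription factor, 120.1-fold higher (66.9 to 241), the serine protease HTRA1 at 37.2 against 0.362. RASD1, a small GTPase, was at 661 against 26.6, the calmodulin-binding protein PCP4 at 39.1 against 0.749, SYNDIG1L at 99.2 against 3.41, the potassium channel KCNJ5 at 26.8 against 0.301 and the adhesion receptor ADGRD2 at 119 against 5.42. On the lower side in F1 were SMAD7, an inhibitor of TGF-beta signalling, at 0.122 against 107, CEL at 2.82 against 305, FABP5 and FABP4 at 1.09 and 0.150 against 162 and 42.6. The secreted protein CTHRC1 was at 11.7 against 464, DPYSL3 at 0.660 against 51.7, TMEM72 at 4.20 against 162 and RSPO3, which enhances WNT signalling, at 0.0739 against 26.4.

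Cholesterol synthesis and uptake stood furthest above its random lists, with 14 of 18 members higher in F1, 1 lower and a median of 1.53 (percentile 100). HMGCS1, an early enzyme of the pathway, was at 380.5 against 39.1, MSMO1 at 288 against 57.7 and DHCR7, its final enzyme, at 129 against 17.2. In gonadotropin and cAMP signalling, 4 of 17 were higher and 2 lower (median 0.23, percentile 99.94). PDE4D, a cAMP phosphodiesterase, was at 59.0 against 3.16 and ADCYAP1R1, the receptor of the peptide PACAP, at 16.2 against 0.535. The 50 cytosolic ribosomal protein genes had 6 higher and 0 lower, with a median of 0.74 (percentile 100) that ranged from 0.63 to 1.15 under 5 other scalings, and RPLP0 was at 3421 against 1406. Immediate early genes had 4 of 11 higher and 0 lower by log2(FPKM + 1) (median 0.28, percentile 99.9). CTGF was at 93.3 against 34.8 and JUN 2.29-fold higher (2.01 to 2.61), while by the ratio of FPKM values, which is larger than on that scale, FOSL2 was 2.11-fold lower (1.60 to 2.82) and FOS 1.95-fold lower (1.45 to 2.64). Of the 11 members 5 were below 0, and with a filter at an FPKM of 5 the list lay within its random lists (percentile 83.7).

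The cell cycle median of -2.64 (percentile 0) included RRM2, which makes deoxynucleotides, 17.9-fold lower (14.1 to 23.2), TK1, thymidine kinase, 14.9-fold lower (10.8 to 21.2). The kinase CDK1 was 13.0-fold lower (10.03 to 17.0) and UBE2C at 4.85 against 60.5. The WNT and NOTCH list had 11 of 21 lower and 0 higher (median -1.07, at the floor -0.98, percentile 0.02). WNT6 was at 1.10 against 27.2, the receptor FZD1 at 7.89 against 50.6 and AXIN2, a feedback target of WNT, at 4.39 against 13.3. Granulosa identity and the inhibin family had 8 of 17 lower and 2 higher (median -0.95, percentile 0.40). FST was at 0.625 against 30.4 and AMH at 0.779 against 18.2. INHBA was at 53.3 against 9.48 and the oestrogen receptor ESR1 at 17.0 against 1.34. This list came to lie within its random lists with a pseudocount of 5 (percentile 7.73), without a filter (8.21) and with a filter at an FPKM of 5 (15.05). Clock genes had 6 of 15 lower and 0 higher (median -0.95, percentile 2.26). BHLHE41 was at 0.816 against 27.6, BHLHE40 at 8.12 against 35.5 and PER2 at 2.10 against 11.3. The clock lay within with a pseudocount of 5 (percentile 3.78) and after median-ratio scaling (2.69). Oocyte and germ cell markers had 10 of 12 lower (median -1.53, ZP2 at 0.443 against 33.4) and surface epithelium 3 of 5 (median -1.62, EPCAM at 2.40 against 19.2), both below their random lists, though surface epithelium lay within with a pseudocount of 5 (percentile 14.6) or without a filter (26.3).

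The other lists lay within their random lists in F1 against F5. Under some scaling the sign changed for 10 of these medians, namely steroidogenesis, BMP and TGF-beta signalling, junctions, the zona pellucida, growth factors, apoptosis, heat shock, glycolysis, oxidative phosphorylation and reference genes. Steroidogenesis had 6 of 17 higher and 4 lower, with a median of -0.16 and a mean of 0.12. HSD17B1, which reduces oestrone, and NR0B1, a repressor of steroidogenic genes, were at 4.33 and 4.88 against 38.3 and 33.6. The zona pellucida list had 2 of 4 higher and 2 lower (median 0.04, mean -0.40), with ZP3 7.45-fold higher (7.42 to 7.48) and ZPD at 4439 against 1181. In ovulation and prostaglandin genes, with 3 of 16 higher and 7 lower (median -0.78), the matrix proteases ADAMTS1 and ADAMTS9 were at 1.22 and 3.07 against 22.6 and 78.7. The protease inhibitor SERPINE2 was at 0.906 against 19.5, and PTGS2, the inducible prostaglandin synthase, at 4.32 against 0.708. BMP and TGF-beta signalling had 2 of 21 higher and 6 lower (median -0.34), with the BMP antagonist GREM1 at 23.6 against 1.42 and SMAD3 at 176 against 33.4. Cell junctions had 3 of 18 higher and 3 lower (median -0.16, mean 0.09), with CLDN5 at 108 against 5.87 and CDH3 at 9.53 against 68.3. Growth factors had 5 of 18 higher and 2 lower (median -0.04), with IGF2 at 6.34 against 131 and IGFBP5 at 176 against 35.5, and VEGFA was at 158 against 152. Extracellular matrix had 9 of 23 lower and 1 higher (median -0.60, COL4A3 at 118 against 251), EGF receptor ligands and MAPK 5 of 13 lower (median -0.76, DUSP1 at 1.00 against 9.36). Cell cycle inhibitors and cyclins D had 4 of 12 lower (median -0.63, CCND1 at 11.2 against 30.4), and apoptosis 4 of 21 lower and 1 higher (median -0.22, TNFRSF10B at 3.88 against 37.0). Glycolysis had 2 of 22 lower and 1 higher (median -0.11, HK2 at 34.0 against 3.29, PFKFB3 at 37.6 against 188), heat shock 2 of 29 lower and 1 higher (median -0.28, CANX at 252 against 84.3). Oxidative phosphorylation had 1 of 37 higher (median -0.15, NDUFA4 at 214 against 88.8), and reference genes 2 of 24 higher and 2 lower (median -0.17, TFRC at 6.53 against 24.8). Theca and smooth muscle markers had 5 of 7 lower (median -1.14, FBN1 at 0.136 against 5.73), but without a filter they lay above their random lists (percentile 98.9). Endothelial markers had 1 of 5 higher and 1 lower (median -0.91) and leukocyte markers 1 of 5 higher and 1 lower (median -0.79, CD74, the invariant chain, at 133 against 40.5). No red cell marker reached an FPKM of 1 in either library.

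**Figure D3:**
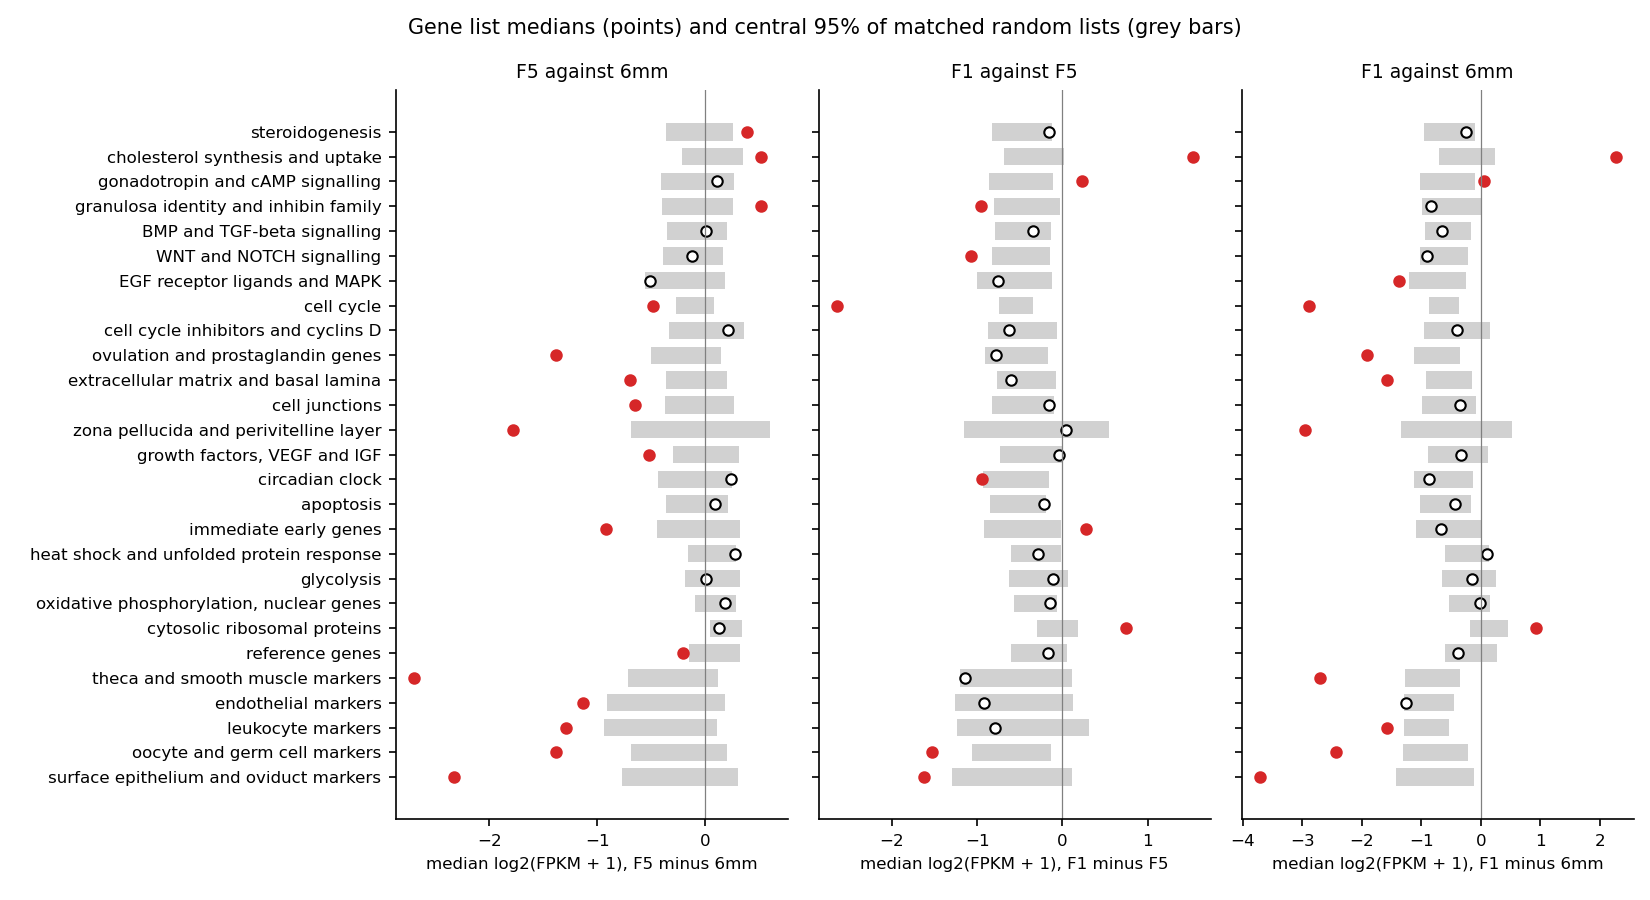
Median log2(FPKM + 1) difference of 27 gene lists in the 3 comparisons, with red points outside and open points within the central 95% of random lists matched on expression, which the grey bars show. The cell cycle list lay at -2.64 and cholesterol synthesis and uptake at 1.53 in F1 against F5.

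In F1, 599 of 11758 genes were at least 2-fold higher than in F5 and 2697 lower, with 168 and 612 at 4-fold, where counting noise alone gave 104. The split depended on scaling: lower genes made up 81.8% of those 2-fold different as deposited and 63.0% (975 higher, 1659 lower) after median-ratio scaling, which moved the median of all genes from -0.53 to -0.17. Relative to the median gene, which takes out a shift of all genes by construction, 1226 were higher and 1132 lower. With ZP3 left out of the library totals, an alternative added after seeing the data, 752 were higher and 2173 lower, and scaled to the same sum 497 were higher and 3126 lower (86.3% lower).

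**Figure D4:**
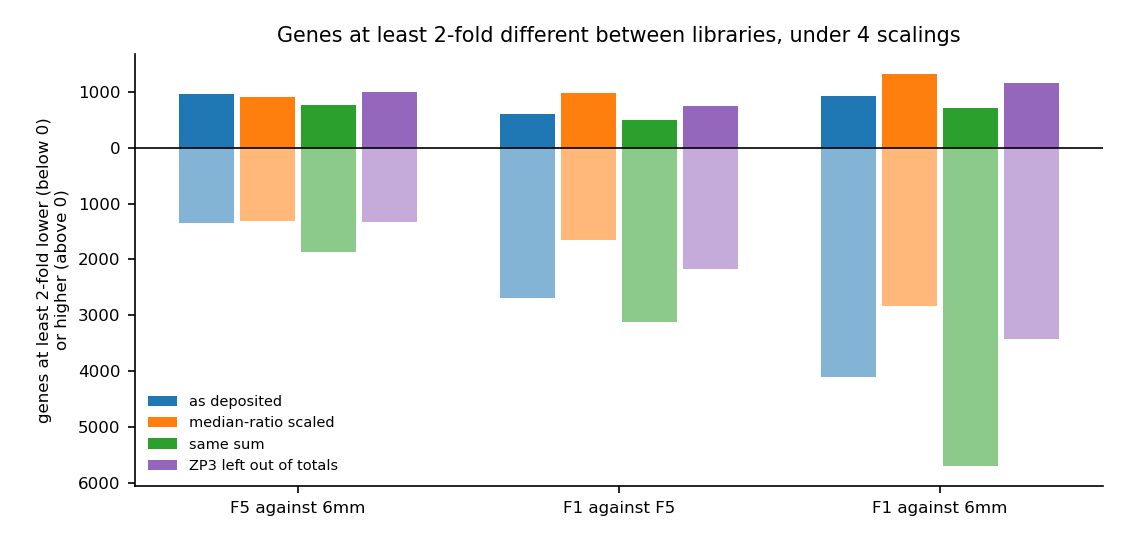
Number of genes at least 2-fold higher (above 0) and lower (below 0, paler) in the 3 comparisons under 4 scalings of the libraries. In F1 against F5, 2697 genes were lower as deposited and 1659 after median-ratio scaling.

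Comparing F1 with 6 mm sets the ends of the series side by side. STAR was 279-fold higher in F1 (193 to 421), CYP11A1 214-fold (145 to 331), HSD3B2 28.8-fold (27.7 to 29.9) and LHCGR 49.2-fold (44.2 to 55.0). NPC2, which binds cholesterol in lysosomes, was at 22487 against 175, 129-fold higher (124 to 133). AMH was 493-fold lower (347 to 726), FST 464-fold lower (323 to 693), INHBB 185-fold lower (118 to 308) and ZP2 413-fold lower (254 to 722).

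Other genes with the largest differences were RASD1 at 661 against 1.64, KCNH2 at 312 against 0.936, NR5A2 at 143 against 0.255, ZPD at 4439 against 42.4, SYNDIG1L at 99.2 against 0.185, the transcription factor DMRT2 at 144 against 0.859 and PGF at 949 against 11.4 on the higher side. On the lower side, COL1A1 was at 0.221 against 276, SMAD7 at 0.122 against 205, COL3A1 at 0.0767 against 185, TAGLN at 0.118 against 163, ACTG2 at 0.157 against 132 and GIF at 0.0555 against 104. These 6 had 1 to 3 reads each in F1.

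Cholesterol synthesis and uptake had 14 of 18 higher and 0 lower (median 2.26, percentile 100). HMGCS1 was 13.7-fold higher (12.7 to 14.7) and the cholesterol carrier STARD4 at 15.5 against 1.52. Ribosomal proteins had 19 of 50 higher and 0 lower (median 0.92, 0.61 to 1.31 under the other scalings). Gonadotropin and cAMP signalling had 4 of 18 higher and 0 lower, and its median of 0.05, above its random lists (percentile 99.4), was -0.18 when scaled to the same sum. In the cell cycle list 47 of 48 were lower (median -2.89, percentile 0). BIRC5, which guards cell division, was 27.7-fold lower (20.4 to 38.6) and MKI67, a proliferation marker, at 0.199 against 4.06. EGF receptor ligands and MAPK had 10 of 16 lower and 0 higher (median -1.37, percentile 0.73). The ligand HBEGF was at 0.609 against 8.29 and DUSP6, induced by MAPK, at least 61.4-fold lower against the floor (exact lower limit 49.4). With a filter at an FPKM of 5 this list lay within its random lists (percentile 3.96). Ovulation and prostaglandin genes had 16 of 22 lower and 1 higher (median -1.91, CEBPB at 1.87 against 35.7), extracellular matrix 18 of 30 lower and 3 higher (median -1.58, COL6A1 at least 598-fold lower against the floor, exact lower limit 485). The zona pellucida list had 4 of 6 lower and 2 higher (median -2.95, at the floor -2.89, mean -0.94), with ZP3 19.5-fold higher (19.3 to 19.6).

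Markers of other cells were lower in F1 beside these groups, and whether such cells gave the lower matrix, protease and zona pellucida genes was not tested. Those at least 2-fold lower were 19 of 19 for theca and smooth muscle (median -2.70, at the floor -2.40) and 13 of 16 for leukocytes (median -1.58, at the floor -1.36). The same held for 12 of 15 markers of oocyte and germ cells (median -2.43) and 7 of 10 for surface epithelium, with 1 higher (median -3.71, at the floor -3.08), all below their random lists. With a pseudocount of 0.1 the leukocyte list lay within too (-0.90 from its random median). Endothelial markers, with 10 of 12 lower and 1 higher (median -1.25, at the floor -1.17), lay within theirs.

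Lists within their random lists in F1 against 6 mm were steroidogenesis (8 of 19 higher, 7 lower, median -0.25, mean 0.94) and granulosa identity and the inhibin family (6 of 19 higher, 8 lower, median -0.84). So were BMP and TGF-beta signalling (6 of 26 higher, 8 lower, median -0.65, but above with a filter at an FPKM of 5, percentile 99.4) and WNT and NOTCH signalling (1 of 23 higher, 11 lower, median -0.90). INHBA was 48.9-fold higher (33.4 to 74.4), SMAD2 8.47-fold higher (8.28 to 8.66) and WNT6 93.9-fold lower (60.6 to 154). Cell junctions (2 of 19 higher, 6 lower, median -0.35), growth factors (6 of 19 higher, 6 lower, median -0.33, mean 0.01), and cell cycle inhibitors and cyclins D (2 of 12 higher, 4 lower, median -0.40) were too. Also within were the clock (3 of 15 higher, 5 lower, median -0.86), apoptosis (2 of 21 higher, 4 lower, median -0.44), immediate early genes (1 of 12 higher, 5 lower, median -0.66) and heat shock (2 of 30 higher, 5 lower, median 0.10, mean -0.22). The same was true of glycolysis (4 of 22 higher, 1 lower, median -0.15, mean 0.06), oxidative phosphorylation (1 of 37 higher, 1 lower, median -0.01) and reference genes (2 of 24 higher, 4 lower, median -0.39). Of the reference genes, GAPDH was lower under every scaling run (-0.73, -0.34 by median ratio) and ACTB changed sign (-0.34, 0.05 by median ratio).

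In F1, 930 of 12482 genes were at least 2-fold higher than in 6 mm and 4100 lower, with 344 and 1168 at 4-fold, where counting noise alone gave 114. Lower genes made up 81.5% of these as deposited and 68.1% (1324 higher, 2830 lower) after median-ratio scaling, which moved the median of all genes from -0.64 to -0.30. Scaled to the same sum they made up 89.0% (702 higher, 5701 lower, median -0.91). Relative to the median gene 1880 were higher and 1771 lower, where a shift of all genes is again taken out by construction. The sign of 6 list medians changed under some scaling: steroidogenesis, gonadotropin signalling, junctions, heat shock, glycolysis and oxidative phosphorylation.

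Over the 3 stages, most of 12812 genes (8113) as deposited differed less than 2-fold in both steps. In 1953 the F1 step alone was down, in 942 the F5 step alone, and in 333, among them AMH, FST and ZP2, both were down. In 426 the F1 step alone was up, as for LHCGR, in 461 the F5 step alone, as for INHA, and in 92, among them STAR, CYP11A1, HSD3B2, INHBA, ZP3 and ZPD, both were up. A further 411, with INHBB, WNT4 and CEL, were up and then down, and 81 down and then up. F5 enters both steps, so its own noise adds to the last 2 classes. The classes depend on scaling: down in the F1 step alone were 1114 genes after median-ratio scaling and 2316 when scaled to the same sum, and up in that step alone 745 and 342.

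Positions of the main genes, as the files give them and with the genome build not given in the sources used here, were as follows. STAR (ENSGALG00000003242) lies on chromosome 22 from 2263879 to 2266815, CYP11A1 (ENSGALG00000001417) on chromosome 10 from 2056283 to 2064888 and HSD3B2 (ENSGALG00000014764) on chromosome 1 from 77954029 to 77969647. LHCGR (ENSGALG00000009095) lies on chromosome 3 from 7505304 to 7524818 and FSHR (ENSGALG00000009100) on the same chromosome from 7340937 to 7418777. AMH (ENSGALG00000024368) lies on chromosome 28 from 1956623 to 1960825, INHA (ENSGALG00000011234) on chromosome 7 from 21555004 to 21556682, INHBB (ENSGALG00000028770) on chromosome 7 from 25068118 to 25068894 and WNT4 (ENSGALG00000004790) on chromosome 21 from 6300381 to 6312118. ZP3 (ENSGALG00000001559) lies on chromosome 10 from 2131957 to 2134350 and NPC2 (ENSGALG00000010237) on chromosome 5 from 37207826 to 37210000.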

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

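Leaving ZP3 out of the library totals was chosen only after the results were seen; the other alternatives were fixed before the data were examined. Under all 9 alternatives each of the 324 differences of at least 2-fold of named genes kept its direction, and 272 stayed at 2-fold or more. The kept direction holds by construction and is no check. A pseudocount cannot turn a sign, a filter leaves a gene's values as they are, and the rescalings moved each gene by less than 2-fold. Of 54 gene counts under the alternatives, 43 were within 1.5 times the count reported. With a pseudocount of 5, which shrinks low genes by construction, the counts higher and lower were 482 and 456 for F5 against 6 mm, 329 and 1095 for F1 against F5, and 585 and 1788 for F1 against 6 mm. With a filter at an FPKM of 5, which leaves fewer genes, 834 were lower in F5 than in 6 mm. F1 against F5 gave 975 and 1659 by median-ratio scaling and 952 and 1677 by upper quartile scaling. List medians, given here as distances from the random median, kept their place inside or outside the random lists in 689 of 727 cases. Many of these cases could hardly change, since a rescaling moves a list and its random lists by nearly the same amount. Lists that stayed outside kept their direction too, while a change of side of lists that stayed within was not counted. The following kept their direction but came to lie within their random lists. With a pseudocount of 0.1 this was leukocyte markers in F1 against 6 mm (-0.90). With a pseudocount of 5 it was the granulosa and inhibin list in F5 against 6 mm (0.25) and F1 against F5 (-0.19), the clock (-0.23) and surface epithelium (-0.22) in F1 against F5. Without a filter it was cell junctions in F5 against 6 mm (-0.18), and in F1 against F5 the granulosa and inhibin list (-0.23) and surface epithelium (-0.13). With the filter at 5 it was extracellular matrix (-0.37) and growth factors (-0.24) in F5 against 6 mm, endothelial markers, F5 against 6mm (-0.0720), the granulosa and inhibin list (-0.22) and immediate early genes (0.24) in F1 against F5, and EGF receptor ligands and MAPK in F1 against 6 mm (-0.65). With median-ratio scaling it was the clock in F1 against F5 (-0.38). The filters change which genes a list holds; for the other settings the cause was not tested. The side reversed for theca and smooth muscle markers in F1 against F5 without a filter (0.42) and for BMP and TGF-beta signalling in F1 against 6 mm with the filter at 5 (0.67), and in both cases the members differ by construction while further causes were not tested. In 21 cases a list within its random lists came to lie outside. With genes without reads at their floor, 11 of 81 medians moved by over 0.05, by 0.786 at most. An alternative on library-scaled counts was not run, since the values used are FPKM. No paired analysis was possible because each stage has 1 library. Depth limits genes near 3 reads, where ratios have wide counting intervals.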

Other observations

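The tests of ZP3, of depth, of HBAA and of the cell cycle list, and all Gene Ontology terms and genes of this part, were chosen only after the results were seen; the other tests were fixed before their results were seen. Single genes, picked by eye and not tested as a group, differed widely between the libraries. NPC2 stood at an FPKM of 175 in 6 mm, 2452 in F5 and 22487 in F1, the lysosomal protease CTSA at 462, 3197 and 6981, PLBD1 at 151, 1351 and 4339, and the lipid transfer protein PLTP at 24.95, 213 and 649. The relaxin family hormone RLN3 peaked in F5 (1268, 6712 and 1658), as did the hedgehog ligand IHH (235, 728 and 83.2), while STC1, a secreted glycoprotein, was at 11.8, 55.5 and 555. Of 636 Gene Ontology terms in F5 against 6 mm, 102 lay outside their random lists, where about 31.8 would by chance. Amino acid transmembrane transport was among them, with 8 of 22 members at least 2-fold higher and 0 lower (median 0.50), including the transporter of large neutral amino acids SLC7A5, the higher of 2 entries, at 161 in F5 against 27.7 and SLC25A22 at 150.1 against 38.2. Terms were counted by gene entry, and the other SLC7A5 entry, at 90.8 against 15.9, is among the 8 too. Lipid catabolic process had 11 of 57 higher and 5 lower (median 0.29), with GALC, a lysosomal galactosidase, at 275 against 20.2 and CYP26A1, which degrades retinoic acid, at 60.9 against 4.12. Chemotaxis had 11 of 23 lower and 1 higher (median -0.88).

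Some abundant genes have no name in the files. ENSGALG00000027090 had an FPKM of 15515 in 6 mm, 52.2 in F5 and 4.21 in F1. Higher in F1 were ENSGALG00000026592 (chromosome 1, 100373556 to 100373705) at 14161 against 321 in 6 mm and 407 in F5, and ENSGALG00000018386 on the mitochondrial sequence (1297 to 2272) at 1637 against 32.5 and 30.1. The files do not state whether these last 2 entries are ribosomal RNA. If they are, their levels depend on the poly-A enrichment and RNA quality of each library, and they are not read as a difference between the cells.

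More genes were lower than higher in F1. The abundance of ZP3 may account for part of it but not the whole. The median of all genes against F5 was -0.53 as deposited, -0.38 with ZP3 left out of the totals and -0.35 with the 50 most abundant genes left out. Lower genes were 81.8% of those 2-fold different as deposited and 74.3% without ZP3. The unnamed gene with at least 14.3% of 6 mm reads was not left out alone in the comparisons with 6 mm. Depth does not account for the excess of lower genes, since the F1 total differed from that of F5 by -0.360%. The authors' scaling may account for part too: after median-ratio scaling 63.0% of the genes 2-fold different were still lower, which lies between the bounds set beforehand. Scaling and a wide loss of transcripts thus cannot be told apart, because no spike-in fixes the scale. A difference between the stages stays open and was not tested, and neither was a difference in RNA quality or poly-A enrichment of the F1 library.

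Markers of other cell types were higher in 6 mm. Red blood cells are argued against by 1 gene only, chosen after its value was seen: HBAA, which they hold in plenty, ranked 9098 by FPKM in that library. Stroma, smooth muscle or leukocytes in the 6 mm material could be a source, but second lists of their markers, written before they were looked up, fell between the bounds set: of 18 measured stroma and smooth muscle genes 55.6% were at least 2-fold lower in F5, with 4 higher (COL14A1, FMOD, LOXL1 and SMTN) and a median of -1.05 at percentile 0 of its random lists, and of 6 leukocyte genes 50%, with CD40 higher and a median of -0.94 at percentile 4.24. The most abundant members of the first list in 6 mm were COL1A1 (276), COL3A1 (185) and COL1A2 (168), and 2 of its 22 genes, CYP17A1 and CYP19A1, belong to the steroidogenesis list too. Other cells and a change within granulosa cells cannot be told apart here, because each library holds the RNA of all cells in its material together. The second stroma list's low median goes with other cells while its 4 higher members do not, and each stage has 1 library.

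Cell cycle genes were lower in F1 than in F5. Scaling does not account for it, since the list's median was still -2.29 after median-ratio scaling. The cell cycle list lay -1.50 further from its random lists than the nearest of the theca and smooth muscle, endothelial and leukocyte lists, and -1.04 further than surface epithelium, but the first 3 had only 7, 5 and 5 measured genes, which went both ways: FBN1 and EMCN were at 0.136 and 0.344 in F1 against 5.73 and 7.56, and COL1A2, CLDN5 and CD74 at 16.0, 108 and 133 against 10.5, 5.87 and 40.5. From 6 mm to F5, 6 of 48 cell cycle genes were at least 2-fold lower, 1 higher and 41 within 2-fold. In that step 15 of 19 theca and smooth muscle markers, 7 of 12 endothelial and 10 of 15 leukocyte markers were lower. Most cell cycle genes thus stayed within 2-fold in that step. Still, 37 of 48 were below 0 and 11 above, and the list's median of -0.49 lay below its random lists (percentile 0). The cell cycle list thus fell beside these markers, though by less, and this does not separate the 2 explanations. Fewer dividing cells of other types and fewer dividing granulosa cells in F1 still cannot be told apart, because the few markers measured in F1 against F5 go both ways and do not decide it. Either may be a candidate explanation and stays a hypothesis, with 1 library per stage.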
